A study of Mus musculus with 2 samples.

How the data were processed

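RNA-seq values of 2 libraries were used, 1 from wild-type mice and 1 from mice with a K14 conditional deletion of Il9r, both from ear epidermis after 6 days of imiquimod. Per the labels' protocols, ears were soaked in dispase II (1 mg/ml, 37 °C, 1 h), the epidermal layer was taken off under a stereo microscope, RNA was extracted with Trizol, and mRNA libraries were made from 3 µg of total RNA with a TruSeq kit. How many animals gave each library is not given in the sources used here. Groups were taken from the genotype labels, and the columns of the table were matched to the libraries by their names.

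Per the submitters' processing notes, TopHat2 2.0.13 and Cufflinks 2.2.1 were used with the mm10 genome. The annotation release, the options, the use of strand and the scaling between libraries are not given in the sources used here. The deposited values are FPKM per locus, per the file headers, with transcript identifiers that mix RefSeq accessions and transcripts assembled from the reads. The authors also deposited a log2 fold change, a test statistic (a score with no fixed range), a p-value and a q-value per locus, per the file headers. These compare 2 libraries and were copied, not recomputed. The deposited log2 fold change was within 0.001 of log2 of the ratio of the deposited FPKM for 99.96% of loci above 0 in both libraries. FPKM divides by transcript length, so short genes have imprecise values, and reads of near-identical genes can be divided between them. The 3 other deposited tables hold spreadsheet settings and were not used.

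The table held 29246 rows, of which 26264 had a gene name and at least 1 RefSeq transcript. Rows of the same name were summed (22 genes), which left 26242 genes. The 2982 other rows, assembled loci without a RefSeq transcript, held 0.74% of the summed FPKM in the wild-type and 1.26% in the knockout library and were left out of the comparisons. This choice was made after the table was seen. Genes entered with at least 1 FPKM in either library. Differences are log2((knockout FPKM + 1)/(wild-type FPKM + 1)), a scale that understates the difference of low genes; ratios given as a fold are of the FPKM themselves.

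The table gives no counts. Over 2326 and 2337 low single-transcript genes of 3 to 12 kb, FPKM multiplied by length fell into steps, and the lowest step was taken as 1 fragment. It gave 24200000 and 31400000 fragments, with a next step at a ratio of 2.03 and 1.99, and single genes scattered around the step by 12.4% and 12.8%. A value of 1 fragment per kb is then worth about 0.041 FPKM in the wild-type and 0.032 FPKM in the knockout library. These depths are estimates, so no counting intervals are given.

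With 1 library per genotype, no test across animals was possible and no p-value was computed. Genes were counted at 2-fold. A total of 35 gene lists (pathways, epidermal layers, cell type markers and quality controls) and the rule for named genes were fixed before the data were examined, with 2 more lists defined by symbol (ribosomal protein and mitochondrially encoded genes). The 24 lists with at least 5 genes past the filter were placed by the percentile of their median log2 difference among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list outside the central 95% was called apart; 11 lists were, where 1.2 would be by chance with independent genes. Members of a list are co-regulated, so a percentile describes these 2 libraries and is no p-value. Lists were matched to the table by symbol, older symbol, RefSeq synonym or merged locus.

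The named genes are Il9r, Il9, Il2rg and Krt14; the 12 highest and 12 lowest log2 differences among genes with at least 5 FPKM in either library, leaving out unnamed loci, small RNAs and pseudogenes; in each list up to 4 members with the largest absolute difference and the 3 most abundant; and the reference and sex-linked genes. Other genes named, such as Ifit1, Zbp1, Slpi, Parp14 and H2-K1, were picked after their values were seen. The positions printed are those of GENCODE M21 on GRCm38, the same assembly as mm10. Genes within 10 Mb of Il9r were found by their start positions in a RefSeq gene list.

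The steps were tested on simulated data. With Poisson counts at the estimated depths, 100% of 100 genes raised 3-fold and 0% of 100 genes raised 1.5-fold, all of at least 5 FPKM, were counted at 2-fold among 11886 genes. Of 100 unchanged lists of 20 genes 5 were called apart, and of 100 lists raised by 0.3 on the log2 scale 100 were. A simulated library of 30000000 fragments was estimated at 29990000. It was made with the transcript lengths that the estimate uses, so it checks the calculation and not the depths of the real libraries. Alternatives were other pseudocounts, filters, scalings and size thresholds, unmatched random lists and list means. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and blastn 2.17.0+ to align gene copies.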

Results

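RNA was sequenced from the ear epidermis of mice whose ears had received 5% imiquimod cream for 6 consecutive days. Imiquimod is an agonist of Toll-like receptor 7, and its repeated application produces psoriasis-like skin inflammation in mice. The epidermal sheets came from wild-type mice and from mice in which Il9r, the gene of the interleukin-9 receptor, had been deleted conditionally through keratin 14 (K14), a keratin of basal keratinocytes. The question was which epidermal transcripts differ when keratinocytes lack this receptor during the imiquimod response. There was 1 library per genotype and no replicates, so no difference given here could be set against a spread between animals. The values were FPKM (fragments per kilobase of transcript, scaled to library size). From the steps between the lowest values, the wild-type library was estimated to hold about 24200000 fragments and the knockout library about 31400000.

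The targeted gene, Il9r (ENSMUSG00000020279, minus strand of chromosome 11, 32187541 to 32200279 in GRCm38), was near the floor of both libraries. It was listed at 0.039 FPKM in the wild-type library and at 0.011 FPKM in the knockout library, which corresponds to about 3 and about 1 fragments. These values were too low to check the genotype labels, and the deleted part of the gene is not given in the sources used here. Il9, the ligand, was listed at 0 in both libraries. Il2rg, the common gamma chain that pairs with the receptor, was at 4.33 FPKM in the wild-type library and 3.11 FPKM in the knockout library. Krt14, the keratin gene named in the genotype label, was among the most abundant transcripts of both, at 7421 and 8083 FPKM.

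Compared with the wild-type library, interferon-response and antimicrobial transcripts were higher in the knockout library. Langerhans and dendritic cell, hair follicle, and immediate early and heat shock transcripts were lower. Basal, spinous and cell cycle transcripts lay at similar levels. Isg15, an interferon-induced ubiquitin-like protein (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), was 7.32-fold higher, at 2.83 FPKM in the wild-type and 20.7 FPKM in the knockout library. S100a8 and S100a9, the subunits of calprotectin, were 3.40-fold and 2.82-fold higher, reaching 353 and 300.1 FPKM. Pyy, which encodes peptide YY, was at 70.9 FPKM in the wild-type and 5.35 FPKM in the knockout library, and H2-Eb1, an MHC class II beta chain, was at 29.97 and 5.53 FPKM. Il1b, the inflammatory cytokine interleukin-1 beta, was at 14.7 and 4.32 FPKM.

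Of 11886 genes with at least 1 FPKM in either library, 49 were at least 2-fold higher in the knockout library and 41 at least 2-fold lower, on the log2(FPKM + 1) scale. In contrast, 11559 genes lay within 1.5-fold. The median log2 difference, knockout over wild type, was -0.02, and 5% and 95% of genes lay below -0.34 and 0.31. Small RNA genes, whose FPKM is imprecise, made up 8 of the higher and 10 of the lower genes. The counts depended on the pseudocount: with 0.1 FPKM they were 100 and 103, and with 5 FPKM they were 16 and 16. Without small RNA genes 41 were higher and 31 lower; in libraries simulated from the same 11816 genes with no difference, at the estimated depths, at most 1 gene passed in either direction. That simulation holds counting noise alone and no difference between animals.

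**Figure D1:**
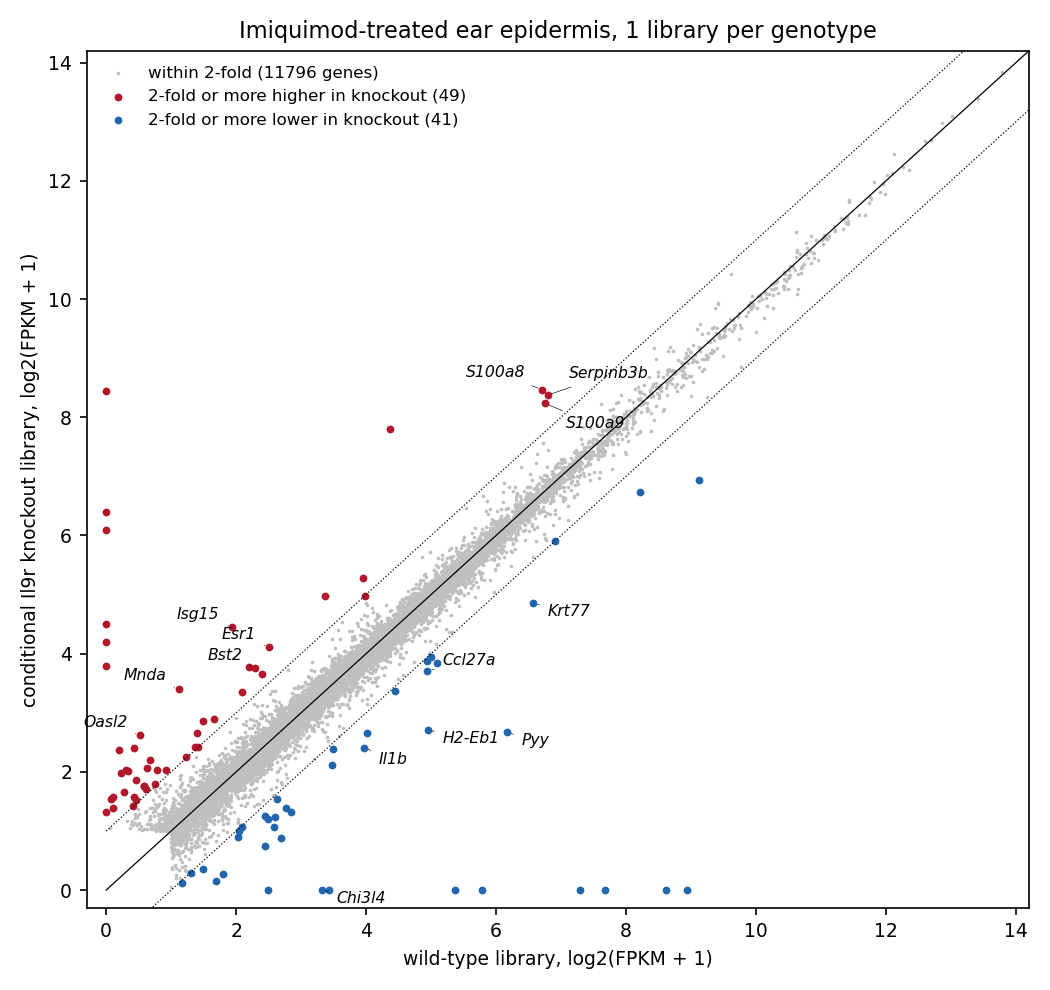
Each point is 1 of 11886 genes, with log2(FPKM + 1) in the wild-type library on the x axis and in the conditional Il9r knockout library on the y axis, 1 library per genotype. The solid line marks equal values and the dotted lines 2-fold differences; red points are the 49 genes at least 2-fold higher and blue points the 41 genes at least 2-fold lower in the knockout library, with Isg15, S100a8, Pyy and H2-Eb1 among those named.

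Among named genes with at least 5 FPKM in either library, the 12 with the highest log2 difference were Isg15, Mnda, Oasl2, S100a8, Esr1, Gypc, Serpinb3b, S100a9, Bst2, Irf7, Mid1 and Oas1a. Esr1, which encodes estrogen receptor alpha, was at 4.65 FPKM in the wild-type and 16.3 FPKM in the knockout library. Gypc, a membrane glycoprotein of red cells and other cells, was at 3.59 and 12.7 FPKM, and Serpinb3b, an epidermal serine protease inhibitor, at 110.2 and 330.8 FPKM. The 12 lowest included Pyy, Chi3l4, H2-Eb1, Krt77, Il1b, Lefty1, H2-T22, Snhg9, Ostf1, Ccl27a and H2-T23. Krt77, a type II keratin, was at 94.3 and 27.8 FPKM. Chi3l4, a chitinase-like gene, was at 8.94 FPKM in the wild-type library and listed at 0 in the knockout library. Mnda, Serpinb3b, Chi3l4, Ccl27a, H2-T22 and H2-T23 belong to families of similar sequence, so their values are uncertain where reads could be divided between copies. The authors' deposited table gave a q below 0.05 for 20 transcribed loci, 10 higher and 10 lower in the knockout library, each with p = 5e-05 and q = 0.041. Isg15, Oasl2, Irf7, S100a8, S100a9, Pyy, H2-Eb1 and Il1b were among the 20 in the authors' deposited table, whose test compares these 2 libraries and not the genotypes.

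All 21 type I interferon response genes that passed the filter were higher in the knockout library, with a median log2 difference of 0.90, and 10 of them were at least 2-fold higher. Of the 21, 12 passed the filter through the knockout library alone, which favours higher genes; the 9 with at least 1 FPKM in the wild-type library were all higher, with a median of 0.66, and without the filter all 28 genes of the list were higher, with a median of 0.67 (percentile 100). The median depended on the pseudocount, at 1.63 with 0.1 FPKM and 0.38 with 5 FPKM. Oasl2, an oligoadenylate synthetase-like protein, was at 0.43 FPKM in the wild-type and 5.14 FPKM in the knockout library. Bst2, which encodes the antiviral protein tetherin, was at 3.88 and 12.5 FPKM, and Irf7, a transcription factor of the interferon response, at 1.81 and 6.29 FPKM. Ifit1 and Zbp1 were at 0.078 and 0.056 FPKM in the wild-type library and at 1.99 and 1.90 FPKM in the knockout library. The more abundant Ifitm3 and Irf9 differed less, at 228 and 300 FPKM and at 11.1 and 18.0 FPKM. The list's median exceeded those of all 10000 random lists matched on mean expression (percentile 100). Cxcl10, an interferon-inducible chemokine, went the other way, at 9.33 and 5.35 FPKM.

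**Figure D2:**
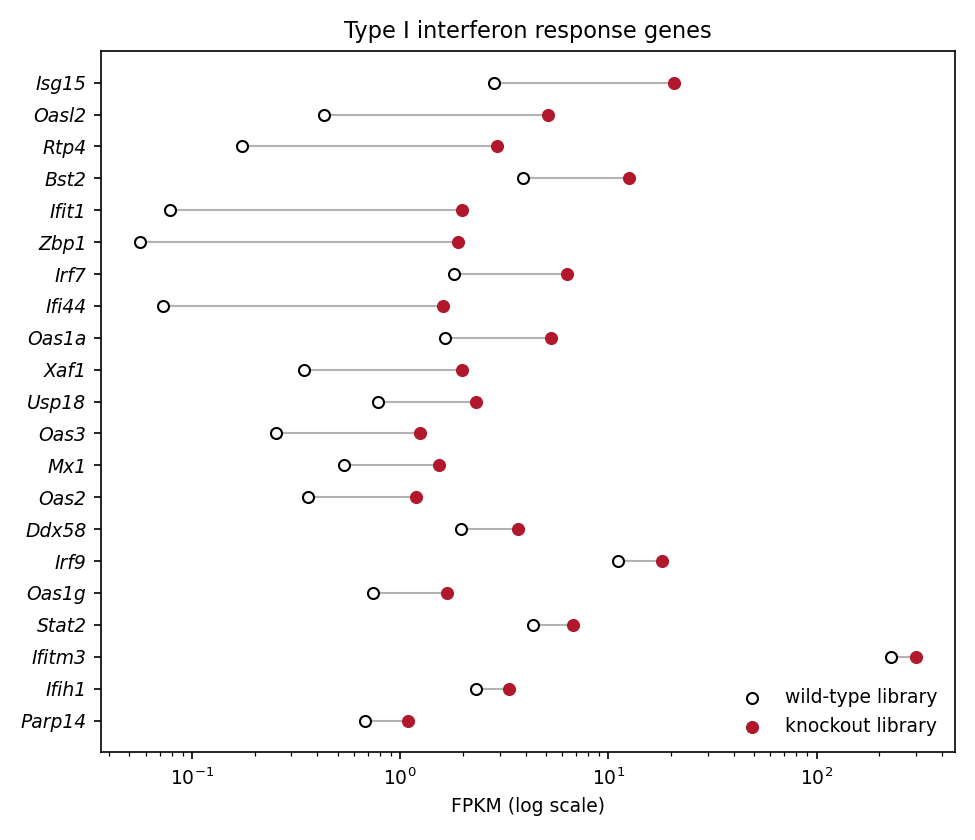
FPKM of the 21 type I interferon response genes that passed the filter, on a log x axis, with the wild-type library as open circles and the knockout library as filled red circles, ordered by log2 difference. The filled circle lies to the right of the open circle for each gene, from Isg15 at 2.83 and 20.7 FPKM to Parp14 at 0.68 and 1.09 FPKM.

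Of 13 antimicrobial protein genes, 10 were higher in the knockout library, 2 of them (S100a8 and S100a9) at least 2-fold, and the median log2 difference was 0.22 (percentile 100). Without the filter that median was 0.10 (percentile 99.9), and the mean of the list was 0.40 (percentile 100). Lcn2, the iron-sequestering lipocalin, was at 11.4 FPKM in the wild-type and 22.3 FPKM in the knockout library. The row that merges the beta-defensin genes Defb4 and Defb6 was at 1575 and 2242 FPKM. Slpi, a leukocyte protease inhibitor, was lower, at 75.8 and 57.5 FPKM. Among 14 genes of the interleukin-1 and interleukin-36 family the median was 0.03 (percentile 88.3). Il1b was the 1 member at least 2-fold lower, while Il18 was at 35.1 and 49.9 FPKM and Il1f6 (Il36a) at 38.4 and 54.3 FPKM.

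The IL-17, IL-22 and IL-23 axis had a median log2 difference of 0.01 over 11 genes (percentile 71.4), with no member 2-fold apart. Its largest difference was in Ccl20, the ligand of CCR6, at 508.9 FPKM in the wild-type and 325.8 FPKM in the knockout library. Nfkbiz, which encodes the regulator I-kappa-B zeta, was at 151.2 and 120.3 FPKM. Neutrophil-recruiting factors had a median of 0.05 over 7 genes (percentile 77.0), with Cxcl1 at 63.5 and 65.7 FPKM and Cxcl2 at 41.8 and 29.0 FPKM. Type 2 cytokines and alarmins had a median of -0.08 over 10 genes (percentile 13.6). Of 10 other chemokines 6 were lower, with a median of -0.22 (percentile 0.14), led by the skin chemokines Ccl27a, at 29.8 and 12.1 FPKM, and Cxcl14, at 22.6 and 11.5 FPKM. With genes under 1 FPKM included, that median was -0.0067 (percentile 59.9), and with a pseudocount of 5 FPKM it was -0.12 (percentile 0.44); the mean of the list was -0.34 (percentile 0.37).

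Interleukin-9 receptor and JAK-STAT genes were lower in 16 of 19 cases, with a median log2 difference of -0.11 (percentile 1.54) and no member 2-fold apart. Cish, a cytokine-induced inhibitor of STAT5 signalling, was at 49.1 FPKM in the wild-type and 35.0 FPKM in the knockout library, and the kinase gene Pim1 at 112.5 and 93.2 FPKM. Stat3 was at 69.6 and 67.9 FPKM and Jak1 at 46.3 and 42.7 FPKM. The list was no longer apart from random lists with a pseudocount of 5 FPKM (percentile 2.59), with a filter of 5 FPKM (4.62) or by its mean (5.45).

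Among keratinocyte layer genes the Lce1 family was higher in the knockout library, and basal and spinous genes were not set apart. Basal keratinocyte genes had a median log2 difference of -0.04 over 16 genes (percentile 39.4) and spinous layer genes -0.07 over 16 genes (percentile 21.3). Krt5 was at 4119 and 4401 FPKM and Krt10, the most abundant transcript of both libraries, at 14182 and 14704 FPKM. Of 31 granular and cornified layer genes 21 were higher in the knockout library, with a median of 0.27 (percentile 100) and none 2-fold apart, but 12 of the 21 were Lce1 genes. Without these, a comparison added after the table was seen, 9 of 19 were higher and the median was -0.028 (percentile 55.6), so the shift of this list rests on the Lce1 genes. All 13 Lce1 genes that passed the filter, which encode late cornified envelope proteins, were higher in the knockout library, with log2 differences from 0.32 to 0.69. Rptn, which encodes repetin, was at 14.97 and 27.96 FPKM, whereas Lor, which encodes loricrin, was at 3467 and 3401 FPKM. The Lce1 genes are similar in sequence and clustered, so they are not independent of each other and their single values are uncertain.

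Of the 18 SPRR and LCE3 genes, which are typical of inflamed or wounded epidermis, 10 were lower and 8 higher, with a median of -0.14 (percentile 0.32). They ran from Sprr1a, at 1025 and 693 FPKM, to Sprr2b, at 13.7 and 21.2 FPKM, the largest difference. By its mean that list was not apart (percentile 9.63). Stress-associated keratinocyte genes had a median of 0.02 over 21 genes (percentile 88.6), with members on both sides: Krt77 was lower, Serpinb3b and Stfa2 were higher, and Krt16 was at 1147 and 948 FPKM. Their mean of 0.12 lay at percentile 99.2. Cell cycle genes had a median of 0.01 over 30 genes (percentile 90.2), from -0.33 for Cdc20 to 0.27 for Birc5. Epidermal barrier lipid genes had a median of -0.04 over 25 genes (percentile 37.7).

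**Figure D3:**
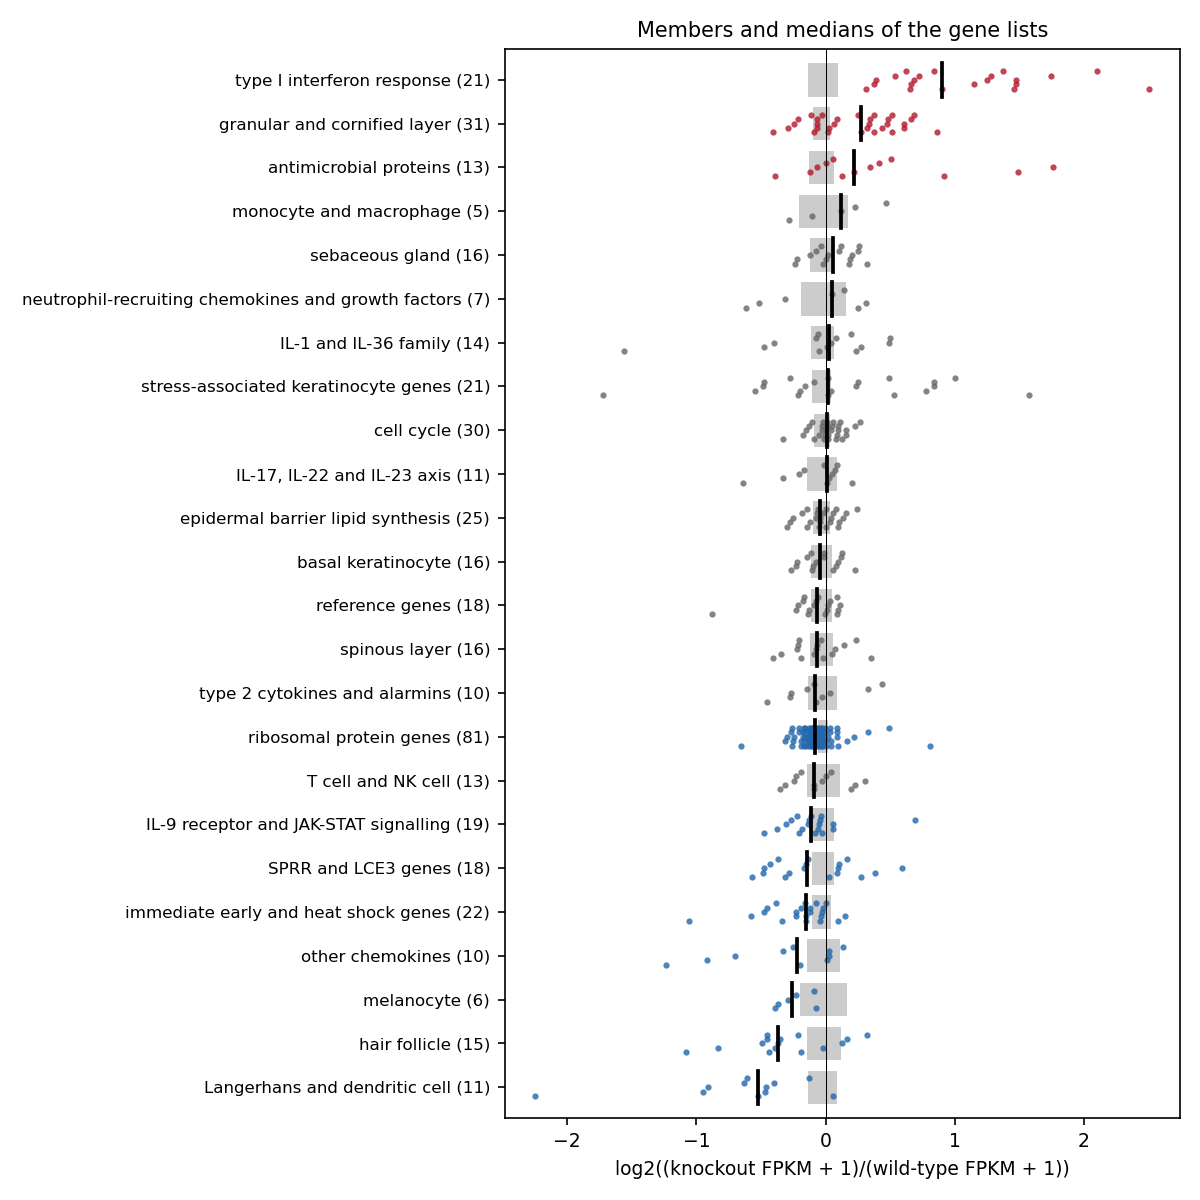
Each row is 1 of the 24 gene lists with at least 5 genes past the filter, with that number in brackets, and each dot is a member's log2((knockout FPKM + 1)/(wild-type FPKM + 1)) on the x axis. Black bars are list medians and grey bands hold the central 95% of the medians of 10000 matched random lists; coloured lists lie outside it, 3 above (red) and 8 below (blue), from a median of 0.90 for the interferon genes to -0.52 for the Langerhans and dendritic cell genes.

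Langerhans and dendritic cell genes were lower in the knockout library in 10 of 11 cases, with a median log2 difference of -0.52 (percentile 0), or -0.30 (percentile 0) without the filter. In the same library hair follicle, melanocyte, and immediate early and heat shock genes were lower too, with medians of -0.37, -0.26 and -0.15. Cd207, which encodes langerin (ENSMUSG00000034783, chromosome 6, 83671215 to 83677857), was at 37.6 FPKM in the wild-type and 19.5 FPKM in the knockout library. The class II genes H2-Aa and H2-Ab1 were at 94.2 and 48.4 FPKM and at 136.2 and 89.1 FPKM, and the costimulatory gene Cd86 at 5.72 and 3.34 FPKM. H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674) differed most, at -2.25. These class II genes are clustered on chromosome 17, so the members of the list are not all independent of each other. T cell and NK cell genes had a median of -0.09 over 13 genes (percentile 11.4), with Cd3g at 8.89 and 11.2 FPKM and Thy1 at 50.3 and 49.4 FPKM. Monocyte and macrophage genes had a median of 0.12 over 5 genes (percentile 92.8), with Cd68 at 4.36 and 4.84 FPKM.

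Hair follicle genes were lower in 12 of 15 cases, with a median of -0.37 (percentile 0), or -0.15 (percentile 0) with a pseudocount of 5 FPKM. Krt71 and Krt25, keratins of the inner root sheath, were at 5.17 and 1.92 FPKM and at 4.80 and 2.26 FPKM. All 6 melanocyte genes that passed the filter were lower, with a median of -0.26 (percentile 0.56), and Pmel was at 5.72 and 4.19 FPKM. That list was not apart by its mean (percentile 2.60) or with genes under 1 FPKM included (7.53), and its median was -0.11 with a pseudocount of 5 FPKM. Sebaceous gland genes had a median of 0.06 over 16 genes (percentile 96.8), with Scd1 at 732 and 722 FPKM. Markers of neutrophils, fibroblasts, skeletal muscle, adipocytes, Schwann cells and erythroid cells each had 3 genes past the filter, those of eosinophils and basophils and of cartilage 2, those of endothelial cells 1, and those of mast cells and B cells 0. These lists were not compared, and mitochondrially encoded genes were not analysed here.

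Immediate early and heat shock genes, which respond to handling of tissue as well as to stimuli, were lower in 19 of 22 cases, with a median of -0.15 (percentile 0.10). Klf2 was at 29.6 and 13.7 FPKM and Atf3 at 380.4 and 272.8 FPKM. Ribosomal protein genes had a median of -0.08 over 81 genes (percentile 0.08), but their mean was not apart (percentile 6.90), and after scaling on the upper quartile the median was -0.050 (percentile 0.11). Reference genes had a median of -0.06 over 18 genes (percentile 20.1), with Actb at 1596 and 1376 FPKM and Gapdh at 850 and 869 FPKM. Xist was at 32.9 and 30.7 FPKM, and the Y-linked genes Kdm5d, Uty and Eif2s3y were listed at 0 in both libraries, with Ddx3y at 0 and 0.0067 FPKM.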

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

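The limits of 5 FPKM and 2-fold used here were chosen after the table was seen. Outside the comparisons, 28 loci assembled from the reads, with no RefSeq transcript, had at least 5 FPKM in the knockout library and were at least 2-fold above their wild-type value, and 6 of these were listed at 0 in the wild-type library. In the other direction, 8 such loci had at least 5 FPKM in the wild-type library and were at least 2-fold lower in the knockout library, with 0 of them listed at 0. The most abundant assembled locus carries the gene name Filip1l and was at 1267 FPKM in the wild-type and 2289 FPKM in the knockout library, a log2 difference of 0.85. The authors' table gives no RefSeq transcript for these loci, and no explanation was tested.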

How the results depend on the processing

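The row-wise count, the count without small RNA genes, the cornified list without Lce1 genes and the 1 FPKM filter on keratin-associated protein genes were added after the data were seen. No list and no named gene changed direction past its threshold under any alternative run, and 5 of the 11 lists called apart stayed so in all of theirs: interferon response, antimicrobial, Langerhans and dendritic, hair follicle, and immediate early and heat shock. The granular and cornified list lost its call and its sign without Lce1 genes (-0.028). The interferon median ran from 0.38 (pseudocount 5 FPKM) to 1.63 (0.1 FPKM) and the Langerhans median from -0.30 (no filter) to -0.61 (pseudocount 0.1 FPKM). Of 13 lists not apart, 12 stayed so. Centring on the median gene moves a list and its random lists alike, so that alternative could not change the call of any list.

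The 49 higher and 41 lower genes became 100 and 103 with a pseudocount of 0.1 FPKM, 16 and 16 with 5 FPKM, 156 and 171 at 1.5-fold, 11 and 12 at 4-fold, and 140 and 89 when each deposited row was counted alone, which adds the assembled loci. With at least 5 FPKM required the higher genes were 24, since fewer genes entered. The other 13 counts were within 1.5 times the reported ones, among them 41 and 31 without small RNA genes. With a pseudocount of 1 no gene under 1 FPKM in both libraries can reach 2-fold, so removing the filter could not move the counts.

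The call of the interleukin-9 receptor and JAK-STAT list was lost by its mean (-0.10), with a pseudocount of 5 FPKM (-0.075) and with a 5 FPKM filter (-0.10). It was lost by the mean for the SPRR and LCE3 genes (-0.093), melanocyte genes (-0.24) and ribosomal protein genes (-0.068), and without a filter for other chemokines (-0.0067) and melanocyte genes (-0.090). Stress-associated keratinocyte genes were called apart by their mean (0.12). The cause was not tested. Of 203 named genes 19 crossed 2-fold, each under another pseudocount. At the 5 FPKM filter 6 lists (T and NK cell, hair follicle, melanocyte, macrophage, neutrophil-recruiting and other chemokines) had under 5 members and no value. The authors' table has no mark for tested rows, so genes with p below 1 stood in for it (49 and 41), and normalizations of counts were not run because the values are FPKM.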

Other observations

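The tests of counting noise, of leukocyte markers (with and without the Langerhans list), of differences between animals, of Cd207 and of the ribosomal protein gene copies were chosen after the values they use had been seen; the others were fixed before their values were seen. Keratin-associated protein genes, which encode matrix proteins of the hair shaft and were grouped after the table was seen, were low in both libraries. Of 45 above 0 FPKM in either library 32 were lower in the knockout library and 13 higher, with a median log2 difference of -0.20. Of the 14 with at least 1 FPKM in either library 13 were lower, but 12 of the 14 passed that filter through the wild-type library alone, so the difference itself largely decided which were counted. Krtap7-1 was at 4.47 and 0.69 FPKM and Krtap8-1 at 4.61 and 1.29 FPKM, while Krtap3-2 was higher, at 2.77 and 4.64 FPKM. The hair follicle list showed the same direction, and the sebaceous gland list did not stand apart.

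The interferon-response genes were higher in the knockout library, with a median log2 difference of 0.90. The values argue against a bias of GC content or transcript length. The median lay at percentile 100 among lists matched on mean FPKM, GC content and length, whose central range was -0.10 to 0.09. The percentile of 100 among lists matched on mean FPKM alone is the one that called the list apart, so it is no separate test of counting noise. Of the 21 genes past the filter, 12 passed through the knockout library alone. Without the filter all 28 genes of the list were higher and 0 lower. Counting noise at low FPKM would put genes on both sides of 0, so these values argue against it. Transcripts carried by more leukocytes in the knockout preparation would come with leukocyte markers that are higher by about as much. The pooled markers of Langerhans and dendritic cells, T and NK cells, macrophages and neutrophils had a median of -0.19 over 32 genes. Of these markers, 25% and 75% lay below -0.41 and 0.05. Of these 32, 11 are the Langerhans and dendritic cell genes already seen to be lower, and they pull the median down. The other 21 had a median of -0.089, with 25% and 75% of them below -0.23 and 0.19 and the largest at 0.47. Of these 21, 13 are T cell and NK cell genes, with a median of -0.089 and a largest value of 0.30. This argues against more T or NK cells that carried the interferon-response transcripts themselves. The markers cannot decide whether leukocytes acted on other cells, because that need not raise the markers by as much. The 5 macrophage genes had a median of 0.12 and the 3 neutrophil genes -0.19, too few to decide for those cells. Cells outside these lists were not tested. A difference between individual animals unrelated to genotype cannot be told apart from an effect of the deletion, because there was 1 library per genotype. A stronger interferon response of the epidermis without the receptor may be a candidate explanation and remains a hypothesis for replicated animals. In the wild-type library Il9r was at 0.039 FPKM, about 3 fragments, and Il9 was listed at 0, so little receptor transcript was seen there. Hair follicle, melanocyte, and immediate early and heat shock genes were lower in the knockout library, so a difference between the epidermal preparations was not excluded.

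The Langerhans and dendritic cell genes were lower in the knockout library, with a median of -0.52. Bias of GC content or transcript length was argued against by percentile 0 among lists matched on both. The lower genes were not MHC class II genes alone, since Cd207, which is no class II gene, differed by -0.91. Cd207 belongs to the list and its value had been seen, so it cannot decide how much of the shift is lower class II expression. Fewer Langerhans cells in the knockout preparation may be a candidate explanation; a second list of myeloid genes gave a median of -0.20 over the 10 genes past the filter (7 of them lower). That median was apart from matched random lists (percentile 0.28), on the side of fewer cells, but lies between the bounds set beforehand for and against it, -0.3 and -0.1, so fewer cells and lower expression per cell cannot be told apart. Hair follicle and melanocyte genes were lower in the same library (medians of -0.37 and -0.26), as were immediate early and heat shock genes, which respond to handling of tissue as well as to stimuli (19 of 22 lower, median of -0.15, percentile 0.10), so a difference between the epidermal preparations that is not limited to Langerhans cells was not excluded. The larger difference of H2-Eb1 was not explained by reads divided with H2-Eb2, since their summed FPKM differed by -2.24. A response of Langerhans cells to the loss of the receptor in keratinocytes stays open and was not tested.

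Ribosomal protein genes and their near-identical copies differed in opposite directions. Gm15772, a copy of Rpl26, was at 19.7 and 222.2 FPKM, Gm8210, a copy of Rpl29, at 557.2 and 121.1 FPKM, and Rpl34-ps1 at 869 and 462 FPKM. Transcripts of copy and parent aligned at 99.5%, 99.4% and 99.4% identity. Reads divided differently between near-identical copies may account for this, because the summed FPKM of parent and copy differed by at most 0.16 on the log2 scale over the 3 families. Gm15772 and Gm8210 are 2 of the 20 loci with a q below 0.05 in the authors' deposited table; no biological explanation was tested.

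Genes within 10 Mb of Il9r on chromosome 11 were not set apart: the median absolute log2 difference of 56 such genes was 0.097, at percentile 21.8 among matched random lists, and 0 of them were 2-fold apart. H2-Eb1, H2-T23 and H2-T22, 3 of the 12 lowest named genes, lie at 34305867, 36029773 and 36037128 on chromosome 17 (GRCm38 starts). H2-K1, a classical class I gene in the same region, was at 241 and 208.5 FPKM.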
